A study of Mus musculus with 6 samples.

How the data were processed

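RNA was sequenced from 6 libraries of mouse ventral midbrain cultures, 3 with a scramble hairpin and 3 with a hairpin against circRmst. Per the labels' protocols, 2 to 3 wells per condition were harvested, total RNA was depleted of ribosomal RNA, and libraries were made with a kit that keeps the strand. Per the labels, 3 independent cultures were sequenced. The labels do not say which libraries share a culture.

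The deposited counts are whole numbers of reads or fragments per gene, with 1 table per library and 42396 genes, and the authors did not pool the libraries. The authors' genome build was GRCm38 (mm10), and reads were converted with bcl2fastq 2.20, per the submitters' processing notes. The aligner, the counting tool and its strand setting are not given in the sources used here. The deposited FPKM values are fragments per kilobase of transcript, scaled to the fragments of the library, in the layout of Cufflinks per the file headers, and Cufflinks 2.2.1 is named in the submitters' processing notes. Those notes also name DESeq2, with no version. Of 39744 gene positions in the FPKM tables on chromosomes, 39731 were identical to the RefSeq table of GRCm38, so that table was used for positions and gene types. The count tables list 2379 genes a second time with a suffix, as copies on alternate sequences, and reads shared between such copies can be split in ways that differ between libraries. Overlapping genes, and copies of a gene with nearly identical sequence, are uncertain for the same reason.

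The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts. Genes were filtered with filterByExpr, which left 17439, libraries were scaled by TMM, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The design held the group alone. Intervals are at 95%. CPM values are TMM-scaled, and a log2 fold change is knockdown against control. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over lists with at least 5 tested members. The same lists were tested with an estimated correlation and with fry. There were 37 lists of functions, cell types and RNA quality, of which 36 were tested. The list of mitochondrial messenger RNAs could not be tested, since 0 of its 13 members are in the count tables. The FPKM tables hold 2 entries with names of that list, ND1 and ND6. The entry ND1 spans bases 2750 to 15286 of the mitochondrial genome and so other genes too, ND6 (13553 to 14070) among them. The histone list was matched through older symbols, 26 of 26.

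The groups, tests, gene lists, named genes and most alternatives were fixed before the data were examined. The named genes were Rmst; among genes past the threshold, the 10 with the largest change in each direction at a mean of at least 1 CPM with no overlap between the groups; up to 4 genes past the threshold of each list or, where none passed, up to 2 with the smallest p; and, where fewer than 10 genes passed, the 10 with the smallest p. Genes that did not pass are given as values, and some of the genes this rule names are not reported here.

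The alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, leaving out each library in turn, an adjusted p under 0.1, a test for a change beyond 1.2-fold, and limma on log2 FPKM with a pseudocount of 0.1 or 1 and a mean FPKM of at least 0.5 or no filter. Thinning every library to the smallest total, and leaving out structural RNA genes, were added after seeing the data.

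Depth ran from 27248934 to 43646521 counts per library. The ribosomal RNA gene Rn28s1 took between 1.01% and 4.49% of the counts. The median half-width of the 95% interval was 0.29 log2 units for genes with at least 1 CPM. The fit and the list test were tested on simulated data, 10 sets of counts with the depth and spread of the real libraries. The test called 98.6% of genes changed 4-fold and 0.0657% of unchanged genes, and a list of 28 genes shifted by 0.3 log2 units was called in 10 of 10 sets. Simulated genes were drawn independently, so these shares hold no correlation between genes. Counts of any pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom between 12.8 and 91.4, so no library was counted as a duplicate.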

Results

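Gene expression was measured by RNA sequencing in primary cultures of mouse ventral midbrain, the region that holds the dopamine neurons of the substantia nigra and ventral tegmental area. The cells came from wild-type embryos at embryonic day 14 and were plated at 150000 per well. On the day of plating they were infected with a lentivirus at a multiplicity of 5. The virus carried either a scramble hairpin, as the control, or a hairpin against circRmst, a circular RNA made from the gene Rmst. RNA was collected at 3 days in vitro, depleted of ribosomal RNA and sequenced with paired reads of 150 bases. There were 3 control libraries and 3 knockdown libraries, and per the labels 3 independent cultures. The counts assigned to genes summed to 41982557, 39766471 and 27248934 in control replicates 1, 2 and 3. They summed to 43646521, 35256611 and 40598850 in knockdown replicates 1, 2 and 3. Between 22840 and 24036 genes had a count in a library, and 17439 passed the filter on low counts. The series asks how lowering circRmst changes gene expression in these neurons, beside their shape and migration.

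Rmst, the long non-coding RNA gene from which circRmst is made, did not differ between the groups past the threshold. It lies on chromosome 10 from 92081746 to 92165178 (GRCm38). Its normalised level was 115, 117 and 124 CPM (counts scaled to the size of the library) in control replicates 1, 2 and 3. It was 105, 97.1 and 115 CPM in knockdown replicates 1, 2 and 3. The group means were 118 ± 4.85 CPM in the control and 106 ± 9.02 CPM in the knockdown (SD, n = 3 each). The log2 fold change was -0.16 with a standard error of 0.10 and a 95% interval from -0.38 to 0.05. In edgeR's quasi-likelihood test its unadjusted p was 0.117, and its adjusted p over all genes was 1.00. Compared by replicate number, Rmst was lower in the knockdown at each number. A gene-level count adds linear and circular transcripts of the host gene, so it is no measurement of circRmst and does not check the knockdown. The circular RNA itself was not analysed here.

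**Figure D1:**
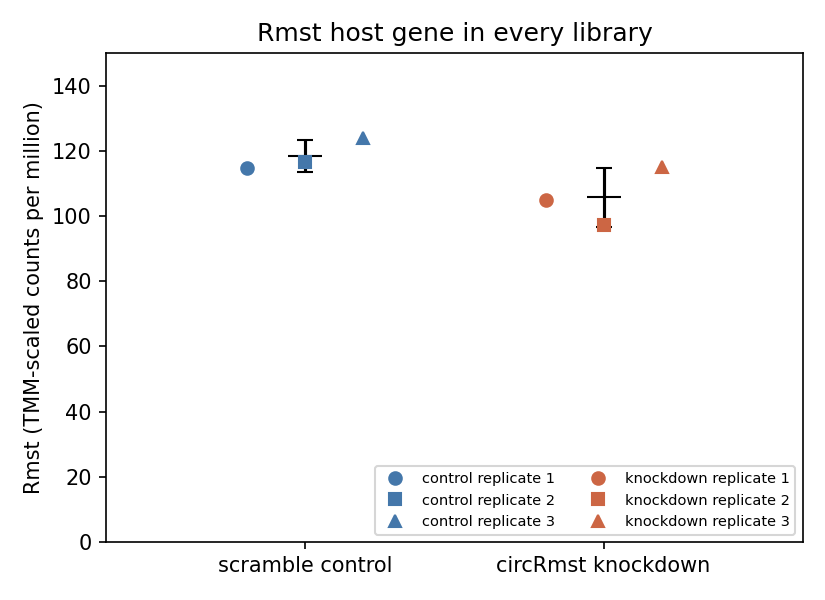
The plot gives Rmst in TMM-scaled CPM for each library, with control libraries in blue and knockdown libraries in orange. Black bars are the group mean and SD of 3 libraries, 118 ± 4.85 CPM in the control and 106 ± 9.02 CPM in the knockdown. The points of the groups overlap slightly, at 115.07 CPM in knockdown replicate 3 against 114.82 CPM in control replicate 1.

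No gene near Rmst passed the test. Within 2 Mb of Rmst, 25 other genes were tested, and 0 had an adjusted p under 0.05 in edgeR's test. Only the long non-coding RNA gene Gm32551 had an unadjusted p under 0.05, and it was barely expressed, at 0.103 ± 0.0588 CPM in the control and 0.297 ± 0.0610 CPM in the knockdown (SD, n = 3 each). Among the well expressed neighbours, Cdk17, which encodes a cyclin-dependent kinase, had a log2 fold change of -0.12 ± 0.09 (SE). Nedd1, which encodes a centrosome protein, had -0.06 ± 0.12. Apaf1, which encodes the core of the apoptosome, had 0.13 ± 0.10. Gm32551, Cdk17, Nedd1 and Apaf1 were picked from these neighbours after their values were seen.

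No gene differed between the knockdown and the control cultures at the threshold. Of 17439 genes tested with edgeR, 0 were higher and 0 were lower in the knockdown at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 191 genes, or 1.10% of those tested, where 5% would be 872. Limma voom on the same genes, those past the filter on low counts, also called 0, with 192 at an unadjusted p under 0.05. DESeq2, run without that filter on 28457 genes, called 1 gene, Gm24019, and had 175 (0.61%) at an unadjusted p under 0.05. Limma on log2 FPKM called 0 genes but had shares nearer to 5% at an unadjusted p under 0.05. These were 662 of 14666 genes (4.51%) with a pseudocount of 0.1, 635 (4.33%) with a pseudocount of 1, and 1071 of 26922 (3.98%) with a pseudocount of 0.1 and no filter. Without the filter on low counts edgeR called 11 genes, 5 higher and 6 lower. The libraries of the groups did not overlap in 907 genes, or 5.20% of those tested, where chance gives 10%. Of the 14501 genes with a mean of at least 1 CPM, 95.7% had a 95% interval that lay within a 2-fold change in either direction, and 78.2% had one within a 1.5-fold change. In simulated data with the same depth and spread, the test called 83.2% of genes of at least 1 CPM changed 2-fold and 37.2% of genes changed 1.5-fold. Each simulated set held 50 genes for each size of change, so a change in fewer genes could be called less often. No spread shared by libraries of the same number was simulated.

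The 10 genes with the smallest p are given as values, since none passed the adjustment in edgeR (adjusted p = 1.00 for each). Gm24019 is one of many annotated copies of the gene for U6, the small nuclear RNA of the spliceosome, and lies on chromosome 10 from 79909195 to 79909301 (GRCm38). It had 2, 1 and 3 counts in the control libraries and 19, 45 and 65 in the knockdown libraries, a log2 fold change of 4.21 ± 0.68 (SE). DESeq2 gave it an adjusted p of 0.0032. It has 46 other annotated copies of at least 99% identity that can take the same reads, so its own level is uncertain. The kinase gene Cdk19, whose protein is part of the Mediator complex, was at 24.4 ± 0.208 CPM in the control and 17.7 ± 0.205 CPM in the knockdown (SD, n = 3 each), with a log2 fold change of -0.46 ± 0.10. Another kinase gene, Cdk18, had a log2 fold change of -0.64 ± 0.17. Zdhhc2, which encodes a palmitoyltransferase, had -0.38 ± 0.10, and the transcription factor gene Pbx3 had -0.34 ± 0.10. The p53 target gene Trp53inp1 had 0.39 ± 0.11. Pmaip1, which encodes the pro-apoptotic protein Noxa, had 1.36 ± 0.41, at 0.726 ± 0.149 CPM in the control and 1.86 ± 1.06 CPM in the knockdown (SD, n = 3 each). Much of this rested on knockdown replicate 1, with 134 counts against 47 and 48 in the other knockdown libraries, and without it the log2 fold change was 0.78. The other 3 genes were close to the limit of detection in both groups. Fndc11 had -2.40 ± 0.61, Cox6a2 had -2.06 ± 0.56 and Gm19710 had 2.26 ± 0.63. Gm19710 overlaps the abundant gene Ubap2l, and since the strand setting of the counting is not given in the sources used here, reads of the 2 genes could not be kept apart.

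Groups of genes gave a different picture under a preset correlation. It did not hold under an estimated one, with the group alone in the design. The estimated correlation and fry were not run with the replicate number as a block. Nor were they run on the simulated counts, so how large a shift of a list they could call is not known. Of 36 lists tested with camera at a preset correlation of 0.01, 4 were called. Genes of the oligodendrocyte lineage were lower in the knockdown as a list, with 19 of 20 tested members below the control and a median log2 fold change of -0.27 (camera adjusted p = 9.46e-06, and adjusted p = 0.999 with an estimated correlation). Genes of dividing cells were lower, with 30 of 32 below and a median of -0.19 (adjusted p = 1.02e-05, and adjusted p = 0.999 with an estimated correlation). Genes of microglia and macrophages were lower, with 16 of 19 below and a median of -0.24 (adjusted p = 0.0028, and adjusted p = 0.856 with an estimated correlation). Genes of p53 signalling and apoptosis were higher, with 23 of 28 above and a median of 0.11 (adjusted p = 9.46e-06, and adjusted p = 0.856 with an estimated correlation). The rotation test fry called 0 lists, with an adjusted p of 0.984 for each of these 4. No member of these lists passed the threshold over all genes, and 0 passed when adjusted over the list alone. With 0 genes called, a Fisher test of each list among the calls could not be made.

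The members of the 4 lists are given as values. In the oligodendrocyte list, Myrf, which encodes a transcription factor of myelination, had a log2 fold change of -0.62 ± 0.21 (SE). Sox10, a transcription factor gene of the whole lineage, had -0.45 ± 0.16. Its most abundant member, the myelin gene Mbp, was at 112 ± 21.9 CPM in the control and 92.8 ± 4.14 CPM in the knockdown (SD, n = 3 each). In the list of dividing cells, Bub1b, a gene of the spindle checkpoint, had -0.35 ± 0.13, and Mcm5, a gene of the replicative helicase, had -0.34 ± 0.14. Its most abundant member, Mki67, was at 91.5 ± 33.4 CPM in the control and 73.0 ± 10.1 CPM in the knockdown. In the list of microglia and macrophages, the lysosomal gene Cd68 had -0.39 ± 0.16 and Tmem119, a gene of microglia, had -0.87 ± 0.39. In the p53 list, Trp53inp1 and Pmaip1, already named, had the smallest p. Mbp and Mki67 were chosen by abundance after their values were seen. Of the tested members, 2 of 20 in the oligodendrocyte list and 2 of 28 in the p53 list also stand in another list.

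Per library, without use of the replicate numbers, the groups overlapped in 3 of the 4 lists. The mean deviation of the oligodendrocyte members from their 6-library mean was 0.26, -0.18 and 0.35 log2 units in control replicates 1, 2 and 3, and -0.09, -0.33 and -0.01 in knockdown replicates 1, 2 and 3 (exact permutation test, two-sided p = 0.3). For dividing cells it was 0.26, -0.16 and 0.15 in the control and 0.06, -0.15 and -0.16 in the knockdown (exact permutation p = 0.3). For microglia and macrophages it was 0.14, -0.01 and 0.19 in the control and -0.26, -0.10 and 0.04 in the knockdown (exact permutation p = 0.2). The p53 list did not overlap between the groups, at -0.10, -0.08 and -0.10 in the control and 0.26, 0.03 and -0.00414 in the knockdown (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). The scores were also compared by number, after seeing the data. For the oligodendrocyte lineage, knockdown minus control was -0.35, -0.15 and -0.35 at numbers 1, 2 and 3. It was -0.40, -0.09 and -0.15 for microglia and macrophages, and -0.20, 0.00487 and -0.31 for dividing cells. For p53 it was 0.36, 0.12 and 0.09. Leaving out 1 library ended some calls and added others, and it leaves the replicate numbers unequal between the groups. The list of dividing cells was not called without control replicate 1 (adjusted p = 0.178) or without knockdown replicate 3 (adjusted p = 0.0868), and that of microglia and macrophages not without knockdown replicate 1 (adjusted p = 0.106). The p53 list stayed called, but without knockdown replicate 1, which had its highest score, the adjusted p was 0.0489. Without control replicate 3 there were 9 lists called, and without knockdown replicate 2 there were 7.

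**Figure D2:**
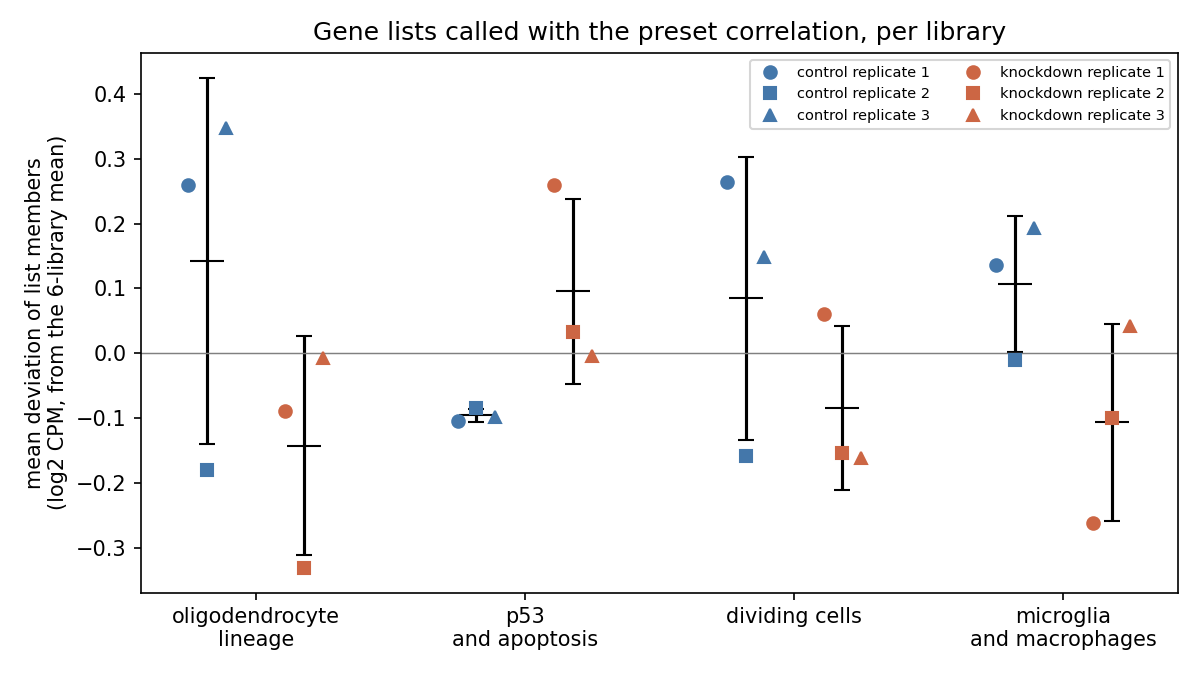
The plot gives, for the 4 lists called with the preset correlation, the mean deviation of the members from their 6-library mean in log2 CPM, with 1 point per library and black bars for the group mean and SD (n = 3 each). Without use of the replicate numbers, control and knockdown libraries overlap in the lists of the oligodendrocyte lineage, dividing cells, and microglia and macrophages, and are apart in the p53 list.

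Markers of the dopamine neurons and of the processes named in the study's aim had medians close to 0. Of 29 tested genes of dopamine neuron identity, 11 lay above and 18 below the control, with a median log2 fold change of -0.04 (camera adjusted p = 0.998). In that list Pbx3, already named, had the smallest p, followed by the synuclein gene Sncg with 0.56 ± 0.41 (SE). The median was -0.03 over 38 genes of neuronal migration, where Rnd3 had 0.12 ± 0.09 and Pafah1b1, the Lis1 gene, had 0.12 ± 0.10. It was -0.02 over 46 axon guidance genes, where the ephrin gene Efnb3 had 0.12 ± 0.10 and the semaphorin receptor gene Plxnd1 had -0.16 ± 0.13. It was 0.02 over 35 genes of the neurite cytoskeleton, where the peripherin gene Prph had -0.63 ± 0.33 and the stathmin gene Stmn4 had -0.24 ± 0.18. Over 35 synapse genes it was -0.02, and over 28 voltage-gated ion channel genes it was -0.04, with the sodium channel subunit gene Scn3b at -0.18 ± 0.09. With all 6 libraries none of these lists was called, and 0 of their members passed when adjusted over the list alone. With 1 library left out and the preset correlation, the ion channel list was called as lower without control replicate 3 (adjusted p = 0.0274) and without knockdown replicate 3 (adjusted p = 5.89e-05). With all 6 libraries its adjusted p was 0.999 with an estimated correlation.

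With all 6 libraries the other lists of function were not called either. The median log2 fold change was 0.03 over 23 genes of the floor plate and Wnt signalling, where Wnt5a had 0.18 ± 0.10 (SE) and Sfrp2 had 0.23 ± 0.15. It was -0.00126 over 24 genes of neurogenesis and Notch signalling, where Notch1 had 0.14 ± 0.09 and Sox3 had -0.23 ± 0.13. A viral vector can set off interferon and inflammatory responses, but both groups were infected, so a response shared by both would not show here. The median was -0.05 over 22 genes of the type I interferon response, where Cmpk2 had 0.26 ± 0.13 and Gbp2 had 0.38 ± 0.22, and 0.05 over 15 genes of inflammation. It was -0.03 over 31 genes of the integrated stress and unfolded protein response, where the transcription factor gene Atf4 had -0.14 ± 0.10. It was -0.03 over 22 genes of heat shock and oxidative stress, -0.03 over 27 immediate early genes, -0.04 over 32 genes of cholesterol and fatty acid synthesis, -0.00485 over 28 genes of glycolysis and hypoxia, and -0.02 over 30 nuclear genes of oxidative phosphorylation. It was -0.03 over 16 genes of small RNA processing, where the Argonaute gene Ago2 had -0.19 ± 0.10. It was -0.03 over 27 genes of splicing and circular RNA regulation, and -0.01 over 33 genes of the extracellular matrix, where the fibronectin gene Fn1 had -0.29 ± 0.12 and the neurocan gene Ncan had 0.24 ± 0.12. With 1 library left out and the preset correlation, 3 of these lists were called as lower. Cholesterol and fatty acid synthesis was called without control replicate 1 (adjusted p = 0.0468) and without knockdown replicate 2 (adjusted p = 0.0388). Splicing and circular RNA regulation was called without control replicate 3 (adjusted p = 0.0274), and the integrated stress and unfolded protein response without knockdown replicate 2 (adjusted p = 0.0128).

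Markers of the remaining cell types and of RNA quality were not called with all 6 libraries and the group alone in the design. The median log2 fold change was 0.00303 over 20 genes of neurons in general, -0.05 over 16 GABAergic, -0.05 over 17 glutamatergic and -0.05 over 12 serotonergic markers, and -0.17 over 7 cholinergic and motor neuron markers. It was 0.04 over 29 markers of astrocytes and radial glia, where the filament gene Gfap had 0.37 ± 0.23 (SE). It was -0.12 over 11 endothelial markers, 0.06 over 26 markers of pericytes, smooth muscle and meningeal fibroblasts, where the collagen gene Col1a1 had 0.35 ± 0.15, and 0.33 over 6 red blood cell genes. It was 0.00905 over 37 ribosomal protein genes, -0.08 over 26 replication-dependent histone genes, -0.04 over 15 nuclear and small structural RNAs, and 0.00369 over 5 genes that mark the sex of the embryos. Mitochondrial messenger RNAs are absent from the counts. In the FPKM values, the entry ND1, which spans other mitochondrial genes too, was at 982 ± 362 FPKM in the control and 613 ± 77.5 FPKM in the knockdown (SD, n = 3 each, exact permutation test on log2 values, two-sided p = 0.2). ND6 was at 63.0 ± 45.8 FPKM in the control and 61.2 ± 41.3 FPKM in the knockdown (exact permutation p = 1). The groups overlapped in both. With 1 library left out and the preset correlation, some of these cell type and RNA quality lists were called. Without control replicate 3, glutamatergic markers were called as lower (adjusted p = 0.0371), and astrocytes and radial glia (adjusted p = 0.0337) and ribosomal proteins (adjusted p = 0.0459) as higher. The glutamatergic score was lowest in replicate 3 of both groups, at -0.40 in the control and -0.27 in the knockdown. Leaving out control replicate 3 thus leaves a low knockdown library without its same-numbered control. Without knockdown replicate 3, ribosomal proteins and the list of pericytes, smooth muscle and meningeal fibroblasts were called as higher (adjusted p = 0.0048 each). Histones were called as lower without control replicate 1 (adjusted p = 0.0044) and without knockdown replicate 2 (adjusted p = 5.57e-10), and red blood cells as higher without knockdown replicate 1 (adjusted p = 0.0397). Over the 32 lists that were not called with all libraries, the lowest adjusted p with the preset correlation was 0.141. In 8 of the 36 lists the median, the mean and the direction of the camera test differed in sign. These were the lists of the extracellular matrix, inflammation, the neurite cytoskeleton, neurons in general, neurogenesis and Notch signalling, heat shock and oxidative stress, ribosomal proteins and glutamatergic neurons.

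**Figure D3:**
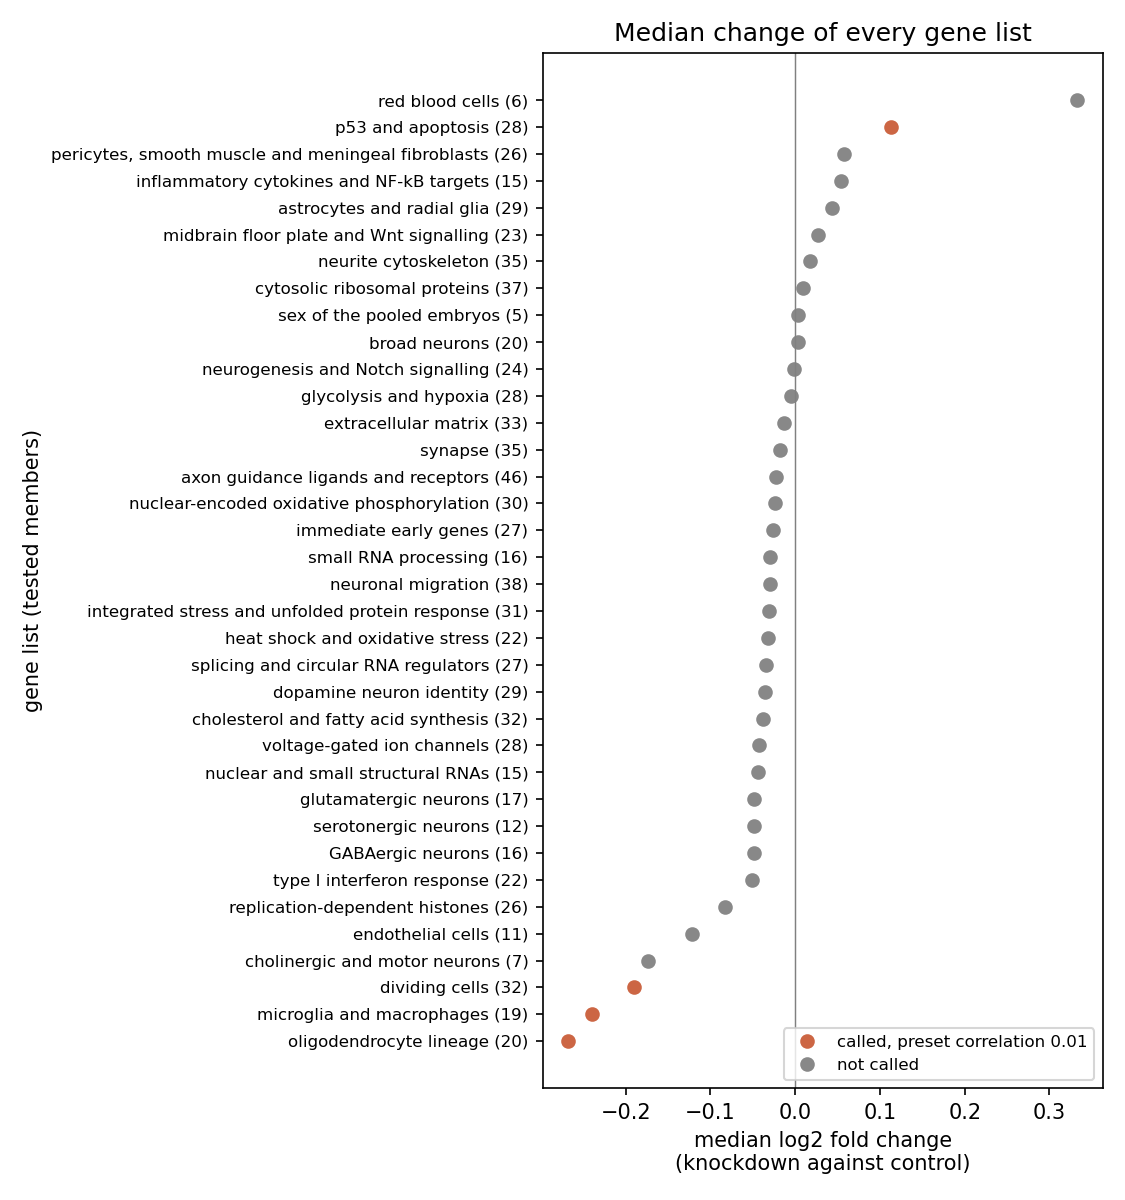
The plot gives the median log2 fold change of the tested members of each of the 36 lists, knockdown against control, with the number of tested members after each name and the 4 lists called with the preset correlation in orange. The 32 lists not called lie between -0.17 and 0.33.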

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

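The thinning and the fit without structural RNA genes were chosen after seeing the data. The count of genes past the threshold stayed at 0 in edgeR under the other scalings, the stricter filter, each library left out (0 in all 6 fits, higher and lower alike), an adjusted p under 0.1 and a change beyond 1.2-fold, and in limma voom and on FPKM. DESeq2 called 1 gene, 1 higher and 0 lower, and with a replicate block also 1, 1 higher and 0 lower. Without the filter on low counts edgeR called 11 genes, 5 higher and 6 lower. The prior degrees of freedom, 6.93 with the filter, then became infinite, so each gene was given the spread of the trend. Of these 11, 10 were tested with the filter, and 1, Gm24019, had no overlap between the groups. Rmst kept its direction with no call in every alternative, from -0.22 to -0.11 with 1 library left out and nearest to 0 on log2 FPKM, at -0.09 with a pseudocount of 0.1 and -0.08 with 1, and 0 of its neighbours were called in any.

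The count of 4 called lists fell to 0 with an estimated correlation and to 0 with fry, both with the group alone in the design. The adjusted p with an estimated correlation was 0.999 for the oligodendrocyte lineage and dividing cells, and 0.856 for p53 and apoptosis and for microglia and macrophages. With fry it was 0.984 for each. With 1 library left out and the preset correlation, 4 to 9 lists were called. The adjusted p then ranged from 3.32e-14 to 0.0274 for the oligodendrocyte lineage, from 7.80e-06 to 0.0489 for p53 and apoptosis, from 4.20e-13 to 0.178 for dividing cells, and from 0.000795 to 0.106 for microglia and macrophages. All 4 stayed called with DESeq2 size factors, the stricter filter, thinning and without structural RNA genes.

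The replicate block gave 0 genes and 258 at an unadjusted p under 0.05 in edgeR, and 6 lists, the 4 named plus cholinergic and motor neurons (lower, adjusted p = 0.0330) and red blood cells (higher, adjusted p = 0.0040). These lists were called with the preset correlation. With an estimated correlation and the group alone, the lists of cholinergic and motor neurons and of red blood cells each had an adjusted p of 0.856. The correlation of deviations from the group means over all tested genes was 0.22, 0.23 and 0.04 for the same-numbered pairs 1, 2 and 3, and 4 of 6 libraries correlated best with their own number. Since 1 pair was under 0.1 over all genes and the labels do not say which libraries share a culture, the block was kept as an alternative. Over the 200 genes most variable across the control libraries, chosen after seeing the data, the same pairs gave 0.65, 0.47 and 0.52, and every other pair was below 0, a hint of shared cultures from the data. If the numbers mark cultures, every fit with the group alone counted differences between cultures as spread, in its p-values and intervals. Compared by number, also after seeing the data, the knockdown's list score was lower in 3 of 3 for the oligodendrocyte lineage and for microglia and macrophages, lower in 2 of 3 for dividing cells, and higher in 3 of 3 for p53.

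Of 1427 values of the 77 other named genes, 1415 kept their direction and side of the threshold, 3 passed (Gm24019, with an adjusted p from 7.33e-09 without the filter to 1.00), and 9 turned in direction with no call, from causes not tested. Rpl15 turned to -0.29, -0.28 and -0.29 on log2 FPKM with a pseudocount of 0.1, of 1, and of 0.1 unfiltered. With a library left out, Stmn4 ranged from -0.37 to 0.014 (above 0 without control replicate 1) and Lhx5 from -0.020 to 0.20 (below 0 without knockdown replicate 1). Ddx3y ranged from -0.081 to 0.26 (below 0 without control replicate 3 or knockdown replicate 2), and Eif2s3y from -0.11 to 0.16 (below 0 without control replicate 3 or knockdown replicate 1).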

Other observations

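Some genes of brain patterning had levels that followed the replicate number of the libraries in both groups. The genes given here were chosen after their values were seen, and whether such genes follow the number as a group was not tested. Zic1, a transcription factor gene of the dorsal neural tube, was at 42.8, 15.3 and 2.19 CPM in control replicates 1, 2 and 3, and at 39.4, 16.1 and 2.08 CPM in knockdown replicates 1, 2 and 3. Zic4 was at 14.1, 2.70 and 0.504 CPM in the control and at 11.3, 2.79 and 0.334 CPM in the knockdown. Barhl1, a homeobox gene, was at 8.32, 26.8 and 8.70 CPM in the control and at 8.80, 25.9 and 8.55 CPM in the knockdown. Lef1, a transcription factor gene of Wnt signalling, was at 6.32, 23.8 and 1.98 CPM in the control and at 4.96, 23.7 and 1.91 CPM in the knockdown. Dmbx1 was at 1.22, 12.3 and 0.539 CPM in the control and at 0.873, 14.4 and 0.765 CPM in the knockdown. Hbb-bs, a haemoglobin gene of red blood cells, was lowest in replicate 3 of both groups and higher in the knockdown at each number. It was at 9.15, 9.45 and 2.77 CPM in the control and at 15.3, 15.96 and 4.35 CPM in the knockdown.

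Transcripts of several cell types were present. Th, the gene of the rate-limiting enzyme of dopamine synthesis, was at 49.9 ± 10.2 CPM in the control libraries (SD, n = 3). Gad2, a gene of GABA synthesis, was at 210 ± 14.1 CPM, and the astrocyte gene Gfap at 88.6 ± 17.7 CPM. Th and Gad2 were chosen after their values were seen.

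Several copies of genes on alternate sequences had many more counts in some libraries than in others of the same group. Rack1_1 had 0, 3326 and 2511 counts in control replicates 1, 2 and 3 and 10, 4 and 2870 in knockdown replicates 1, 2 and 3, while the chromosomal gene Rack1 had between 2010 and 3136. Mfn2_1 had 526 counts in control replicate 1 and between 3 and 8 in the others. Adgrb2_1 had 372 counts in knockdown replicate 1 and between 3 and 13 in the others, and Ttc3_1 had 650 in knockdown replicate 2 and between 25 and 35 in the others. Tmsb10, the gene of a thymosin, was at 584 CPM in control replicate 1 and between 158 and 264 CPM in the others. The mitochondrial transfer RNA gene TrnM was at 9.34 CPM in control replicate 1 and between 0.783 and 1.88 CPM in the others. These genes were chosen after their values were seen.

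Of the tests that follow, the thinning, the splits for gene lists, the estimated correlation and the matchings of libraries were chosen only after the result was seen. The 4 lists called with the preset correlation were set against other causes. A difference in depth is argued against, since 4 of the 4 lists were called after every library was thinned to the smallest total. At least 3 of the 4 lists were called with any 1 library left out, so no single library was needed for all 4 calls. The calls of dividing cells and of microglia and macrophages did end in some of these fits. The preset correlation also called between 5 and 15 lists in the other splits given below. A list that stays called is thus weak ground against a single library that stands apart, and the question stays open. Members moving together more than the preset correlation assumes is a candidate explanation: the lowest estimated correlation of the 4 lists was 0.0987, and 0 lists were called with it. That estimate was made with the group alone in the design, and none was made with the replicate number as a block. The real split called 4 lists, and among the other 9 splits of the 6 libraries into 3 and 3 the highest called 15. All 10 splits called at least as many as the real one, and 10 splits are too few for a share under 0.05. Some of the other splits set replicate numbers against each other, so they may hold differences between cultures. Those with each number once on either side, as in the real split, called 8, 10 and 11 lists. An effect of the knockdown on these cells stays open as untested.

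The real split had 191 genes with an unadjusted p under 0.05, and each of the other 9 splits had more, from 233 to 2444. Splits with each replicate number once on either side, as in the real split, had 233, 311 and 1112. The remaining splits also set replicate numbers against each other. The low share was not seen to the same extent on FPKM: limma on log2 FPKM gave the real split between 3.98% and 4.51%, against 1.10% in edgeR and 1.10% in limma voom on the counts. The fits on FPKM differ from these in unit and gene filter. The FPKM come from Cufflinks, and TMM scaling was used on the counts only. Scaled by library totals in place of TMM, the counts gave 1.03% in edgeR, which argues against TMM as the source of the gap. On the counts, edgeR gave 0.90% with a filter of 1 CPM in 3 libraries (14589 genes) and 2.07% with no filter. These filters alone did not bring the share to that of the FPKM fits, and what else raises it was not separated. A split with many times the real count points to a structure of the samples other than the groups. A single library that stands apart is argued against as the whole cause of the low share in edgeR. The share with an unadjusted p under 0.05 was at most 2.55% with any 1 library left out, under the 5% of unchanged genes. That highest share came without knockdown replicate 3, the library with the lowest share of Rn28s1 (1.01%). It was above the 1.10% of all libraries, so a part played by that library is not excluded. Leaving it out also leaves the replicate numbers unequal between the groups. A culture shared by libraries with the same number may account for part of the low share. With the number as a block 258 genes had such a p, where the highest of the 5 other matchings of control with knockdown libraries had 239. With 6 matchings 1 leads by chance, so this lead alone cannot be told apart from chance, and 258 genes are still 1.48%. Over the 200 most variable genes, chosen after seeing the data, same-numbered pairs correlated at 0.65, 0.47 and 0.52. That is a hint of shared cultures, and it does not test whether they lower the share. For genes past the threshold, the real split had 0 and the highest other 3, so 10 of 10 splits had at least as many, and 10 splits are too few for a share under 0.05.

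Gm24019, the U6 gene copy with 2, 1 and 3 counts in the control and 19, 45 and 65 in the knockdown libraries, might follow a general rise of U6 RNA. The summed CPM of the 45 other copies of at least 99% identity in the count tables had a log2 ratio of 0.059, knockdown against control, with overlapping groups. These copies together held only 20 to 43 counts per library, and how reads that match several copies were counted is not given. Their sum may thus not measure U6 RNA, and it does not decide the question. How reads were shared among identical copies was not tested, nor was an effect of the knockdown on this copy alone.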
